A study of Mus musculus with 10 samples.

How the data were processed

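Spleen B cells of 3 genotypes (UNG+/+, UNG-/- and AID-/-) had, per the labels' protocols, been stained with 5 µM CFSE, a dye diluted at each division, and cultured for 4 days with LPS (25 µg/ml), IL4 (10 ng/ml) and BAFF (20 ng/ml). Cells that had divided at least 5 times were sorted. A fragment of Smu was then amplified from genomic DNA for 25 cycles with a proofreading polymerase, sheared to 100 to 300 bp and made into Illumina libraries with 10 further cycles. The submitters' processing notes name CASAVA 1.7, Novoalign 2.07.04 and SAMtools 0.1.11 without giving their roles. Amplification, shearing and the absence of molecular identifiers mean that reads are not independent molecules, and polymerase and sequencing errors enter every count, which the AID-/- libraries measure.

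Per the file headers, the deposited tables list for each of the 560 positions the number of reads, the number of reads that passed a base quality filter (Phred above 20) and the count of reads for each base substitution, which the authors made from the filtered reads. The deposited fraction for each substitution was, per the file headers, that count over the filtered reads, and recomputing it from the counts gave the deposited values. The counts and filtered reads were used here, and the fraction was recomputed and is printed per 10000 reads. The genome build and coordinates are not given in the sources used here. The authors left out 5 polymorphic positions (225, 376, 454, 455 and 486), and the reference base in the tables differed between AID-/- and UNG libraries at the same 5. These 5 and 1 position with under 1000 reads in a library (position 560) were left out, and 554 remained, 90 of them C and 153 of them G.

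Total quality-filtered base reads ranged from 112909908 (UNG+/+ replicate 1) to 255310423 (UNG+/+ replicate 4), and median coverage per position from 152413 reads (UNG-/- replicate 2) to 409076. Libraries of a group differed by more than counting error, with a chi-square per position between 1.98 and 31.5 over all pairs, so the spread between libraries was taken as the error.

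Groups and replicate numbers were taken from the sample titles. The groups, the comparisons, the tests, the rule for naming positions and most alternatives were set before the data were examined. A library's value was the mean over positions of the fraction substituted, each position weighing alike. Excess was this value minus the mean of both AID-/- libraries at the same positions. C:G positions were classed by the sequence 5' of the C on the strand that carries it, as WRC (74 positions, 33 on C and 41 on G), its subsets WRCY (51), AGCT (12), AGC (31), AAC (13), TGC (13) and TAC (17), SYC (63) and neither (105), and A:T positions as WA (168) or other A (142). Single values were compared by exact two-sided permutation of group labels over 70 assignments for 4 against 4 and 15 for 4 against 2, on log2 excess for motif classes or on the unsubtracted mean where an excess was not above 0. Benjamini-Hochberg adjustment was made over the 6 substitution types and over the 11 motif classes.

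Single positions were tested with edgeR 4.0.16 (quasi-likelihood) in R 4.3.3 on substituted reads, with the logarithm of coverage as offset and all 10 libraries in a fit, at an adjusted p of 0.05, for positions with at least 10 substituted reads in at least 2 libraries. This left 237 C:G and 278 A:T positions, adjusted apart. Such a fit keeps differences in total substitution load, whereas TMM scaling of the substituted reads removes them. DESeq2 1.42.0, limma 3.58.1 on the fraction or its log2 value (pseudocount 1e-05) and quasi-binomial regression were run as alternatives. Other values were computed with Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and figures with matplotlib 3.10.9.

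The named positions were the 10 largest rises and up to 10 largest falls between UNG-/- and UNG+/+ among those past the threshold without overlap between the genotypes, and the 5 highest by mean excess in each genotype. No fall and no A:T position met the rule. Positions named otherwise are said to be so where they appear.

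The edgeR step was tested on simulated data of the same size with 20 changed positions per fold. For UNG-/- against UNG+/+ at 237 C:G positions it recovered 100% of 2-fold rises, 85% of 0.5-fold changes and 55% of 1.5-fold rises, with 3 false calls. For UNG-/- against AID-/- the shares were 75%, 80% and 15% with 1 false call, and for UNG+/+ against AID-/- 65%, 80% and 30% with 2. For 278 A:T positions they were 80%, 85% and 35% with 0 false calls.

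Replicate numbers were checked for pairing by the correlation between UNG+/+ and UNG-/- libraries of the deviations from their group means. At C:G positions libraries with the same number gave 0.551, 0.160, 0.276 and 0.307, and at A:T positions 0.118, -0.0383, -0.0319 and 0.0662. At C:G positions libraries from the same pair of numbers (1 and 2, or 3 and 4) gave 0.143 to 0.551 and those from different pairs -0.546 to -0.126. UNG libraries numbered 1 and 2 also had T to G rates of 0.364 to 0.404 per 10000, against 0.202 to 0.266 for those numbered 3 and 4. Deviations from a group mean cancel within the group, so positive values within pairs bring negative values between pairs. The numbers thus follow a shared step at least in pairs, which may be technical, although no label names a batch. A replicate block was therefore run beside the main tests, with a smallest exact p of 0.125 for sign flips.

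Alternatives set in advance were pooled reads in place of equal positions, trimming of 25 positions at each end, removal of the 5% of positions highest in AID-/- cells, coverage of at least 10000 (523 positions), transitions alone, no subtraction, no count filter, only the groups compared, the replicate block and leaving out each replicate. Chosen after the data were seen were removal of positions within 3 bp of a polymorphic position, each library's own SYC value as background, C:G to A:T left out, a block of replicate numbers 1 and 2 against 3 and 4, separate fits within each of these pairs, and motif values without the 1 position that moves them most.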

Results

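Activated mouse B lymphocytes were sequenced over a fragment of the immunoglobulin switch mu region (Smu), the repetitive intronic sequence upstream of the Ighm constant exons where class switch recombination begins. AID turns cytosine into uracil in this region, and uracil-DNA glycosylase (UNG) removes uracil from DNA. The design set UNG-deficient cells beside UNG-proficient cells to ask how UNG alters the substitutions that AID leaves, with AID-deficient cells as the negative control. There were 4 UNG+/+ libraries, 4 UNG-/- libraries and 2 AID-/- libraries. The measure was the fraction of quality-filtered reads at a position that carried a base other than the reference, given here per 10000 reads. Of the 560 positions, 554 were used, of which 243 were C:G and 311 were A:T. Genome coordinates and build of the fragment are not given in the sources used here, so positions are numbered as in the deposited tables, and a name such as C282 gives the reference-strand base and its position.

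Depth was high in every library. UNG+/+ replicates 1 to 4 held 112909908, 175201086, 176449199 and 255310423 quality-filtered base reads, with a median coverage per position of 155830, 265556, 282647 and 409076 reads. For UNG-/- replicates 1 to 4 the totals were 136738576, 113425148, 204862164 and 136938740, with medians of 194932, 152413, 346208 and 220740. AID-/- replicates 1 and 2 held 166000223 and 221955784, with medians of 249433 and 373574. Reads were PCR copies without molecular identifiers, so any interval on a single library covers counting error only, and the spread between libraries was used as the error throughout. The design text counts mice, but no label says that each library came from a separate animal. The p-values therefore measure only the spread between these libraries, which may be technical. UNG libraries numbered 1 and 2 also differed from those numbered 3 and 4 in sequencing quality, with 98.17 to 98.34% against 98.91 to 99.02% of bases passing the filter away from polymorphic positions. AID-/- replicates 1 and 2 differed likewise from each other, with 98.26% and 99.03%. Any excess within a pair of replicate numbers still subtracts the mean of both AID-/- libraries, so it is not matched for this quality difference. Because of the quality difference, values within each of these pairs of replicate numbers are given beside the main pooled comparisons of UNG-/- with UNG+/+ cells.

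Both genotypes that carried AID had more substitutions at C:G positions than AID-deficient cells. The mean frequency at C:G positions was 28.9 ± 5.26 per 10000 reads (SD, n = 4) in UNG-/- cells and 12.7 ± 0.657 (SD, n = 4) in UNG+/+ cells, against 4.18 and 4.59 in the AID-/- libraries. UNG-/- cells thus stood 24.5 per 10000 above the AID-/- mean of 4.38, a 6.60-fold ratio. UNG+/+ cells stood 8.28 above it, a 2.89-fold ratio. All libraries with AID lay above both AID-/- libraries, and the exact two-sided permutation p was 0.0667 for each comparison, the smallest that 4 libraries against 2 can give, so neither could pass 0.05. The AID-/- libraries had other reference bases at the 5 polymorphic positions, so comparisons with them are not matched for haplotype.

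UNG-/- cells carried a higher substitution load at C:G pairs than UNG+/+ cells. The UNG-/- mean exceeded the UNG+/+ mean by 16.3 per 10000, a 2.28-fold ratio and a mean log2 difference of 1.17 ± 0.145 (SE), and all 4 UNG-/- libraries lay above all 4 UNG+/+ libraries. The exact two-sided permutation p was 0.0286, the smallest that 4 against 4 can give. Among libraries numbered 1 and 2 the ratio was 2.51, and among those numbered 3 and 4 it was 2.04, where the smallest exact two-sided p is 0.333. With libraries paired by replicate number the difference stayed at 16.3 and the exact sign-flip p was 0.125, the smallest that 4 pairs allow. Leaving out any UNG+/+ replicate gave an exact p of 0.0571, although all UNG-/- libraries still lay above all remaining UNG+/+ libraries. With groups of unequal size, another assignment of libraries can give as large a difference of means. This p therefore does not show a loss of separation. UNG-/- replicates 1, 2 and 4 carried a second base at polymorphic positions, and UNG-/- replicate 3, which did not, had 28.2 per 10000 at C:G positions, against at most 13.5 in the UNG+/+ libraries.

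Substitutions at A:T positions stayed near the AID-/- background in both genotypes. Their mean frequency was 1.10 ± 0.0376 per 10000 (SD, n = 4) in UNG+/+ cells, 1.16 ± 0.0513 (SD, n = 4) in UNG-/- cells and 1.07 in AID-/- cells. The difference of 0.0630 between the UNG genotypes was larger than either SD but did not pass the test (exact two-sided permutation p = 0.143). It was 0.0239 within replicate numbers 1 and 2 and 0.102 within 3 and 4.

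The substitutions at C:G pairs differed in kind as well as in number. C:G to T:A transitions averaged 8.03 ± 0.866 per 10000 (SD, n = 4) in UNG+/+ cells and 26.6 ± 5.54 (SD, n = 4) in UNG-/- cells, against 1.12 in AID-/- cells, a 3.31-fold ratio and a log2 difference of 1.71 ± 0.177 (SE). C:G to G:C transversions went the other way, with 1.39 ± 0.252 (SD, n = 4) in UNG+/+ cells and 0.395 ± 0.0551 (SD, n = 4) in UNG-/- cells, a log2 difference of -1.81 ± 0.166 (SE). The UNG-/- level of these transversions was close to the 0.449 of AID-/- cells. C:G to A:T transversions averaged 3.23 ± 0.687 in UNG+/+ cells and 1.94 ± 0.472 in UNG-/- cells (SD, n = 4 each), with 2.81 in AID-/- cells, so the UNG-/- value lay below the background of the control.

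Each type was tested by an exact two-sided permutation test on 4 libraries against 4, with Benjamini-Hochberg adjustment over the 6 types. The exact p was 0.0286 for C:G to T:A and for C:G to G:C, without overlap between the genotypes, and both had an adjusted p of 0.0857. It was 0.0571 for C:G to A:T, with an adjusted p of 0.114. None of the 6 types passed the adjusted threshold, which a family of 6 with a smallest p of 0.0286 can pass only if at least 4 types reach that smallest value together. Within replicate numbers 1 and 2 and then 3 and 4, the UNG-/- to UNG+/+ ratios were 3.56 and 3.01 for C:G to T:A, 0.224 and 0.364 for C:G to G:C, and 0.569 and 0.625 for C:G to A:T. The A:T types averaged 0.613 against 0.618 for A:T to G:C (exact p = 0.8), 0.234 against 0.273 for A:T to C:G (exact p = 0.229), and 0.252 against 0.271 for A:T to T:A (exact p = 0.457), each UNG+/+ first. Within the same replicate numbers their ratios were 0.994 and 1.02 for A:T to G:C, 1.08 and 1.29 for A:T to C:G, where both UNG-/- libraries lay above both UNG+/+ libraries in each pair, and 1.02 and 1.12 for A:T to T:A.

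**Figure D1:**
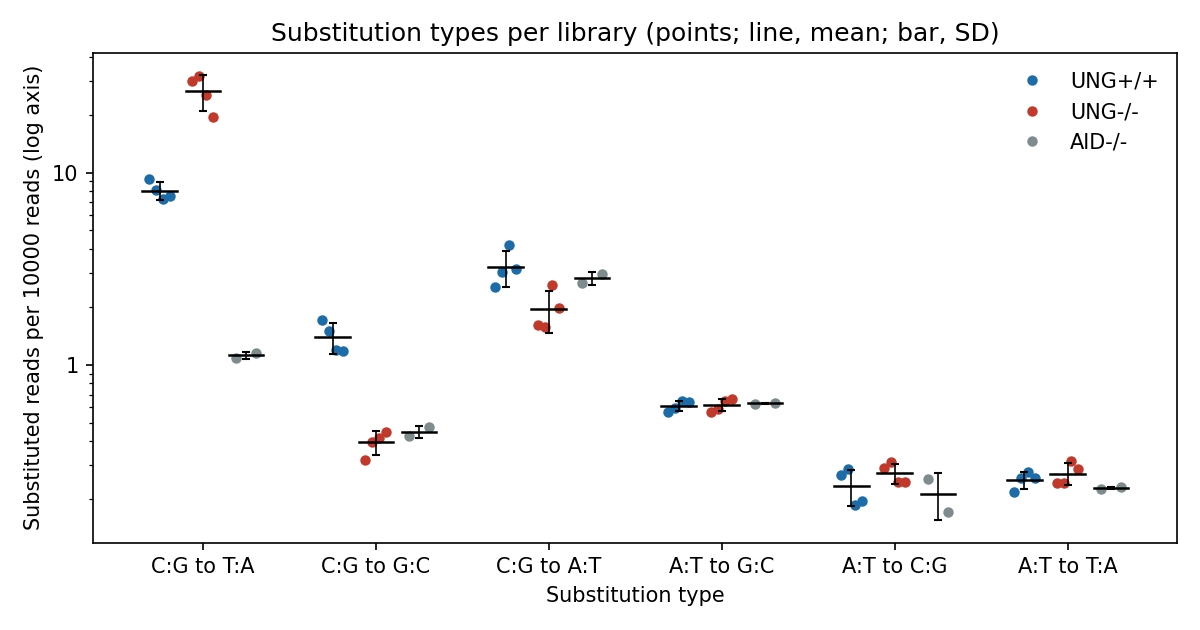
Substituted reads per 10000 (log axis) for each of 6 strand-collapsed substitution types, with a point per library, a line at each genotype mean and a bar for its SD. C:G to T:A averaged 26.6 in UNG-/- and 8.03 in UNG+/+ libraries, whereas C:G to G:C averaged 0.395 and 1.39.

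Transitions made up a larger share of the AID-dependent substitutions when UNG was missing. With the mean AID-/- value subtracted, transitions were 83.5% ± 6.33 (SD, n = 4) of the excess at C:G positions in UNG+/+ cells and 103.8% ± 1.81 (SD, n = 4) in UNG-/- cells. The UNG-/- share exceeded the whole, as the C:G to A:T level in UNG-/- libraries was below that of AID-/- libraries. With C:G to A:T left out, an alternative chosen after the data were seen, the shares were 88.1% and 100.2%. The main difference of 20.3 percentage points had an exact two-sided permutation p of 0.0286, without overlap between the genotypes, and was 17.8 and 22.8 points within replicate numbers 1 and 2 and 3 and 4. Paired by replicate number, it had an exact sign-flip p of 0.125, the smallest possible.

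AID prefers cytosine in WRC context (W is A or T, R is A or G) and avoids SYC (S is C or G, Y is C or T). Substitutions in both genotypes were concentrated at WRC motifs, and UNG-/- cells had the higher excess in every WRC class. Over the 74 WRC positions the excess over AID-/- rose from 24.9 ± 3.70 per 10000 (SD, n = 4) in UNG+/+ to 71.3 ± 15.2 (SD, n = 4) in UNG-/- cells, a log2 difference of 1.50 ± 0.196 (SE). The 12 AGCT positions, which carry overlapping WRC motifs on both strands, had the highest excess, 46.8 ± 6.42 in UNG+/+ and 102.5 ± 23.2 in UNG-/- cells, with a log2 difference of 1.11 ± 0.204 (SE). AAC positions rose from 18.6 ± 4.02 to 77.2 ± 18.5, a log2 difference of 2.04 ± 0.239 (SE), and TAC positions from 18.0 ± 1.95 to 72.5 ± 15.3, a log2 difference of 1.99 ± 0.178 (SE). AGC positions rose from 33.5 to 79.3 and TGC positions from 19.5 to 44.7, with log2 differences of 1.23 and 1.18, and the WRCY subset of WRC rose from 29.2 to 81.4. The subtracted AID-/- level was 5.11 per 10000 at WRC, 4.71 at WRCY, 5.87 at AGCT, 2.54 at AAC, 4.19 at TAC, 6.27 at AGC and 6.12 at TGC positions.

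Outside WRC the signal was far lower. The 105 C:G positions in neither WRC nor SYC rose from 1.57 to 6.15 per 10000, a log2 difference of 2.11 ± 0.436 (SE) over an AID-/- level of 4.25, and that difference was 2.87 within replicate numbers 1 and 2 and 1.34 within 3 and 4. The 63 SYC positions, tested without subtraction since some libraries were below the control, held 3.90 per 10000 in UNG+/+ and 4.50 in UNG-/- cells, against 3.82 in AID-/- cells (adjusted p = 0.377, exact permutation test). When only transitions were counted, SYC had an excess of 0.287 in UNG+/+ and 1.66 in UNG-/- cells, and the class passed with an adjusted exact p of 0.0349. At A:T positions the WA motif had an excess of 0.0714 and 0.150 (adjusted exact p = 0.140), and other A positions had an adjusted exact p of 0.457. Without subtraction WA held 0.921 in UNG+/+, 1.00 in UNG-/- and 0.850 in AID-/- cells. All 4 UNG-/- libraries lay above both AID-/- libraries there, with an exact two-sided permutation p of 0.0667, the smallest that 4 against 2 can give. Other A positions held 1.36 in UNG-/- and 1.34 in AID-/- cells.

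Of the 11 motif classes, 8 passed, each with an exact two-sided permutation p of 0.0286 and an adjusted p of 0.0393, with all 4 UNG-/- libraries above all 4 UNG+/+ libraries. The classes share positions and libraries and are not independent. A smallest p of 0.0286 can pass over 11 classes only if several reach it together. All of the 8 but the class in neither WRC nor SYC are WRC or its subsets, which count the same positions again. With libraries paired by replicate number 0 of 11 passed, each of the 8 classes having an adjusted exact sign-flip p of 0.172, since 4 pairs cannot give less than 0.125 before adjustment. The AGCT class no longer passed without any UNG+/+ replicate (adjusted exact p of 0.0698 to 0.0786), nor did the class in neither WRC nor SYC without any UNG-/- replicate (0.0786), while SYC passed without UNG+/+ replicate 3 and WA without UNG+/+ replicate 2 (0.0393 each). For AGCT and for the class in neither WRC nor SYC, the genotypes still did not overlap in these fits, so separation was not lost. Within replicate numbers 1 and 2 the log2 difference was 1.58 for WRC, 1.23 for AGCT, 2.09 for AAC and 2.14 for TAC. Within replicate numbers 3 and 4 it was 1.42, 0.99, 2.00 and 1.84 for the same classes. Within the former pair and then the latter it was 1.56 and 1.37 for WRCY, 1.29 and 1.16 for AGC, 1.23 and 1.13 for TGC, 0.73 and 1.97 for WA and 0.01 and 0.08 for other A, whereas for SYC it turned, from 0.57 to -0.06.

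C:G to G:C transversions at WRC positions stood above the AID-/- level in UNG+/+ cells and close to it in UNG-/- cells. C:G to G:C substitutions at WRC positions averaged 3.43 ± 0.832 per 10000 in UNG+/+ and 0.468 ± 0.0328 in UNG-/- cells (SD, n = 4 each), with 0.462 in AID-/- cells. At AGCT positions the same type averaged 8.04 in UNG+/+, 0.584 in UNG-/- and 0.556 in AID-/- cells, whereas at SYC it was 0.313, 0.309 and 0.393. Counting transitions alone, the WRC excess was 20.1 in UNG+/+ and 72.0 in UNG-/- cells, a 3.58-fold ratio. Without adjustment, C:G to G:C at WRC and at AGCT each had an exact two-sided permutation p of 0.0286 between the UNG genotypes. The WRC transition excess had the same exact p. At SYC the C:G to G:C difference of -0.00327 per 10000 did not pass that test.

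**Figure D2:**
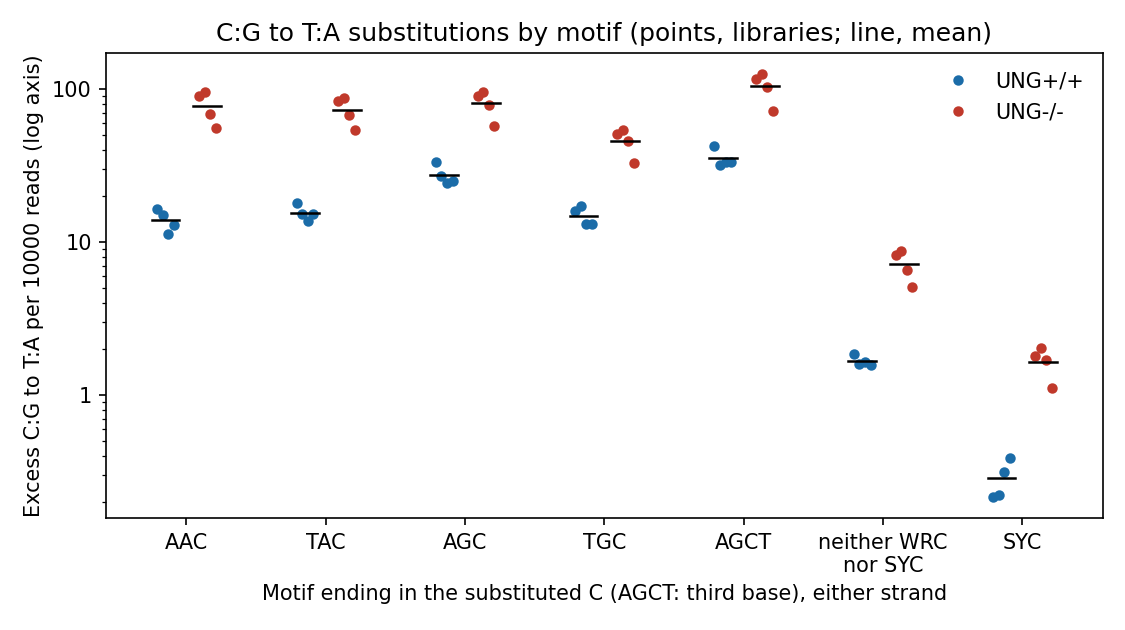
Excess C:G to T:A transitions per 10000 reads over the AID-/- mean (log axis) for C:G motif classes in UNG+/+ and UNG-/- libraries, with a point per library and a line at each mean. AGCT averaged 103.6 in UNG-/- and 35.3 in UNG+/+ libraries, AAC 77.5 and 13.9, and SYC 1.66 and 0.287.

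The preference for WRC over other C:G positions was not shown to differ between the genotypes with all substitutions counted. Its log2 value was 5.66 ± 2.75 (SD, n = 4) in UNG+/+ and 4.13 ± 0.121 (SD, n = 4) in UNG-/- cells (exact two-sided permutation p = 0.314), and the difference was -3.31 within replicate numbers 1 and 2 and 0.25 within 3 and 4. The divisor, the excess at other C:G positions, was only 0.0396 to 2.42 per 10000 in UNG+/+ libraries. Their log2 values therefore ran from 3.16 to 9.56, and the comparison is unstable. With transitions alone the preference was 4.12 ± 0.155 in UNG+/+ and 3.82 ± 0.0326 in UNG-/- cells (SD, n = 4 each), lower by a log2 difference of -0.30 (exact p = 0.0286), with -0.46 and -0.14 within the same replicate numbers. Without subtraction of the AID-/- value the direction turned, to 0.64 (exact p = 0.0571), and without UNG+/+ replicate 3 the difference was -2.36 and passed (exact p = 0.0286). Over all C:G positions the excess at C of the reference strand was higher than that at G in both genotypes, with 10.7 at C and 6.83 at G in UNG+/+ cells and 29.9 and 21.4 in UNG-/- cells. WRC motifs made up 33 of the 90 C positions and 41 of the 153 G positions. The C and G values are thus not matched for motif content and do not by themselves show a strand bias. The log2 C over G preference was 0.64 ± 0.172 and 0.48 ± 0.0465 (SD, n = 4 each), a difference of -0.17 (exact two-sided permutation p = 0.114) that was -0.27 and -0.06 within replicate numbers. It passed without UNG+/+ replicate 3 (exact p = 0.0286 for -0.22) and was 0.0126 (exact p = 0.886) without the 5% of positions highest in AID-/- cells.

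Position by position, substitutions were higher in UNG-/- cells at 69 of 73 WRC sites and at 11 of 60 SYC sites, or at 72 of 73 and 28 of 59 when transitions alone were counted, whereas with TMM scaling 38 WRC and 0 SYC sites were higher. The edgeR test with coverage as offset called 133 of 237 C:G positions at an adjusted p of 0.05, with 131 higher and 2 lower in UNG-/- cells. The genotypes did not overlap at 116 of the 237 positions tested, where chance separates 2.86%, and 114 of these were among the 133. Among WRC positions 69 of 73 were higher, with a median log2 fold change of 1.37 (70 adjusted over the list alone). All 13 AAC positions and all 16 TAC positions tested were higher, with medians of 1.93 and 1.83, as were 29 of 31 AGC, 11 of 13 TGC and 11 of 12 AGCT positions. The 4 WRC positions that did not pass, named after their values were seen, were G451, C452, C457 and C488, with log2 fold changes of 0.41, 0.27, 0.39 and 0.33, and each lay within 3 bp of a polymorphic position. With transitions alone these were 1.57, 0.45, 0.99 and 1.22, and only C452 did not pass (edgeR adjusted p = 0.0610). Of 60 SYC positions 11 were higher and 1 lower (6 higher adjusted over the list alone), and of 104 positions in neither class 51 were higher and 1 lower.

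The largest rises past the threshold without overlap between genotypes were at 10 positions with log2 fold changes of 2.03 to 2.37, and all 10 lay at position 234 or lower. G100, whose motif on the C strand is AACT, rose from 6.20 ± 1.32 to 32.0 ± 7.29 per 10000 (SD, n = 4 each; AID-/- 1.24), a log2 fold change of 2.37 ± 0.213 (SE, adjusted p = 2.25e-25). G189 (AACA) rose from 8.99 to 45.6, C114 (AACA) from 12.6 to 57.6 and G93 (AACA) from 8.12 to 34.8, with log2 fold changes of 2.34, 2.19 and 2.10. Among TAC motifs, G176 (TACA) rose from 8.65 to 40.2, C119 (TACT) from 22.1 to 93.2, C122 (TACA) from 7.68 to 32.3 and G200 (TACC) from 31.05 to 127.4, with log2 fold changes of 2.22, 2.08, 2.08 and 2.04. The other 2 were CAC motifs outside WRC, G234 (CACA) from 7.26 to 33.6 and G232 (CACT) from 20.9 to 85.0, with log2 fold changes of 2.21 and 2.03. AID-/- levels at these 10 positions were between 1.24 and 4.23.

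The most substituted positions were largely shared. In UNG+/+ cells the highest excess stood at C282 (AGCT), which rose from 125.6 ± 23.3 to 285.2 ± 75.6 per 10000 (SD, n = 4 each; AID-/- 6.87), a log2 fold change of 1.18 (adjusted p = 4.75e-06). It was followed by C506 (AACT), from 83.0 ± 18.2 to 284.5 ± 63.5 (AID-/- 2.72), and G40 (TACT), from 74.6 ± 8.33 to 295.1 ± 61.7 (AID-/- 4.43), with log2 fold changes of 1.78 and 1.98. G281 (AGCT) rose from 66.9 to 133.9 and G456 (AGCT), which lies 1 bp from a polymorphic position, from 67.0 to 130.0, with log2 fold changes of 1.00 and 0.96 and AID-/- levels of 3.97 and 4.09. In UNG-/- cells G40, C506 and C282 led, followed by C287 (TACA), which rose from 54.6 to 203.7, and G315 (AACT), from 49.5 to 188.2, with AID-/- levels of 7.97 and 2.80. At C506 the C to G type alone was 35.2 per 10000 in UNG+/+, 1.30 in UNG-/- and 1.15 in AID-/- cells, while C to T was 43.0 in UNG+/+ and 282.6 in UNG-/- cells.

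**Figure D3:**
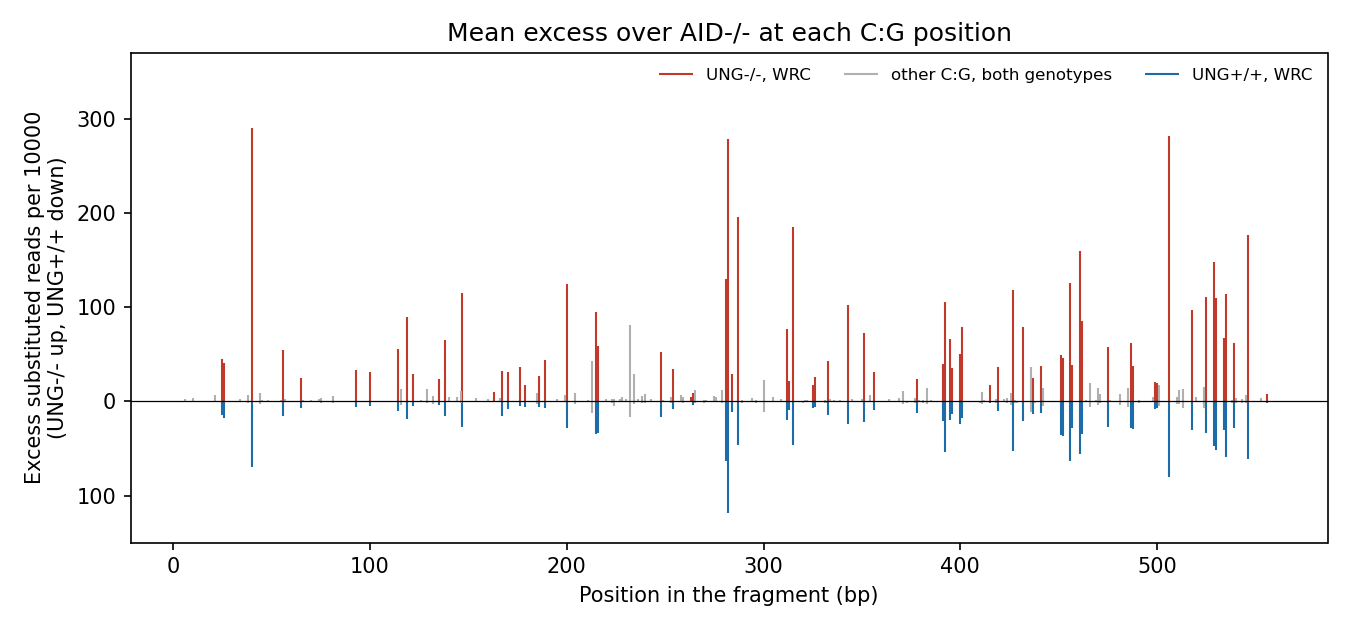
Mean excess substituted reads per 10000 over the AID-/- mean at each C:G position of the fragment, with UNG-/- plotted upward and UNG+/+ downward and WRC positions in colour. The highest bars stand at G40, C282 and C506, where UNG-/- means were 295.1, 285.2 and 284.5 and UNG+/+ means were 74.6, 125.6 and 83.0 before subtraction.

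No lower position was free of overlap between genotypes, and both lower calls are named after their values were seen. C224 (TCCG) went from 7.71 to 5.14 per 10000, a log2 fold change of -0.57 (adjusted p = 0.0312), and lies 1 bp from a polymorphic position. It stood at 10.2 in UNG-/- replicate 3 and at 3.24, 2.84 and 4.24 in replicates 1, 2 and 4, and AID-/- cells had 2.89. G410 (CCCT) went from 3.98 to 2.46 (AID-/- 2.74), a log2 fold change of -0.70 (adjusted p = 0.0189), with UNG+/+ replicate 3 at 7.80. Without that replicate its log2 fold change was -0.16, and with transitions alone it was 0.66. DESeq2 called neither position.

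These calls are relative to coverage. With TMM scaling, which centres the positions, the median log2 fold change over the C:G positions moved from 0.66 to -0.10, and 126 positions were called, 53 higher and 73 lower. Relative to that centre, 38 of 73 WRC positions were higher and 2 lower (C452 and C488), including 13 of 13 AAC, 13 of 16 TAC and 2 of 12 AGCT positions higher, whereas SYC had 0 higher and 40 lower of 60. C282, G281 and G456 no longer passed under TMM, with log2 fold changes of 0.36, 0.19 and 0.14 and adjusted p of 0.340, 0.566 and 0.645. With replicate number as a block 140 positions were called, which included all 133. Fitted apart, the UNG libraries of replicate numbers 1 and 2 gave 151 higher and 1 lower (C224) and those of 3 and 4 gave 86 higher and 1 lower (G410), and all 133 had the same direction within both pairs. With transitions alone 200 of 236 were called, 199 higher and 1 lower (C224), and these included 132 of the 133. By class, 72 of 73 WRC, 28 of 59 SYC and 99 of 104 positions in neither class were then higher.

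Against AID-deficient cells, substitutions stood out at almost all WRC positions in both genotypes. In UNG-/- cells 139 of 237 C:G positions were higher and none lower, among them 72 of 73 WRC, 11 of 60 SYC and 56 of 104 positions in neither class (73, 7 and 56 adjusted over the list alone). In UNG+/+ cells 97 positions were called, 96 higher and 1 lower, among them 70 of 73 WRC, 2 of 60 SYC (G371 and C481) and 24 of 104 higher in neither class. Adjusted over the list alone, 71 WRC, 0 SYC and 16 positions in neither class were higher in UNG+/+ cells, so neither SYC call was kept. The WRC positions that did not pass were C263 (TACG) in both genotypes, where AID-/- cells had 10.0 per 10000, and G163 (AACT) and C415 (AACA) in UNG+/+ cells. The single lower position was C243, with 4.13 in UNG+/+ and 6.72 in AID-/- cells, a log2 fold change of -0.70. These few were named after their values were seen. Under TMM the counts were 88 higher and 109 lower for UNG-/- and 70 higher and 71 lower for UNG+/+ cells, with median log2 fold changes moved by -1.33 and -0.58. With transitions alone 206 of 236 positions were higher in UNG-/- cells, among them 73 of 73 WRC, 32 of 59 SYC and 101 of 104 in neither class, and 154 in UNG+/+ cells, among them 72 of 73 WRC, 11 of 59 SYC and 71 of 104 in neither class. For UNG+/+ cells limma on the untransformed fraction gave 0, with 55 at an unadjusted p under 0.05.

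All 96 positions higher in UNG+/+ than in AID-/- cells were among the 139 higher in UNG-/- cells, where independent lists would share 56.3, although both lists rest on the same controls. Across the 243 C:G positions the mean excess in UNG-/- cells correlated with that in UNG+/+ cells with a Pearson r of 0.940 and a Spearman rho of 0.911. Groups simulated at the AID-/- rate, and so without AID signal, with simulated AID-/- libraries as shared controls, gave means of 0.639 and 0.613. The upper ends of the central 95% of 1000 simulations were 0.788 and 0.701, which show only what shared controls give. The observed covariance was 723.1 (per 10000, squared), against a mean of 0.734 and an upper end of 1.23 in those simulations. Positions are not independent replicates and no p-value is given. Over WRC positions alone the values were 0.893 and 0.897.

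Single A:T positions gave no call with all libraries. The edgeR test called 0 of 278 A:T positions between UNG-/- and UNG+/+ cells, with 18 at an unadjusted p under 0.05. DESeq2 called 0 with 9 at an unadjusted p under 0.05, quasi-binomial regression 0 with 18, limma on the fraction 0 with 21 and limma on its log2 value 0 with 22. Without UNG-/- replicate 2 the edgeR test called 1, position 408, with a log2 fold change of 1.06. Fitted within replicate numbers 1 and 2 it called 0, with 21 at an unadjusted p under 0.05, and within 3 and 4 it called 2, positions 178 and 408 (named after their values were seen), higher in UNG-/- cells by log2 fold changes of 0.67 and 1.14. In simulated data of this size 80% of 2-fold rises and 35% of 1.5-fold rises at A:T positions were recovered, so smaller differences at single A:T positions were not reliably detectable with this number of libraries, spread and depth.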

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

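The tests of other sample groupings, of positions beside polymorphic positions, of motif loss and of carry-over between libraries were chosen after the results were seen, whereas those on background and place along the fragment, and on loss beside a mismatch, were set before their result. Of 100 sets of values in the UNG groups, 3 had a library far from the other 3, and chance gives about 1 in 20. These were the transition share of the excess in UNG-/- replicate 3 (101.1%), the WA excess in UNG+/+ replicate 2 (0.161 per 10000) and the transition excess at AGCT in UNG+/+ replicate 1 (42.3 per 10000).

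Of the 35 ways to part the 8 UNG libraries into equal groups, 1, the real one, gave as many C:G calls as its 133, and the highest of the others gave 5. Were libraries freely exchangeable, this would be a share of 1 in 35, the smallest that these splits can give. Replicate numbers appear to share a step that no label names. The 8 splits that part every number (133 in the real one, at most 1 in the others) are too few for a share under 0.05. A strain difference linked to genotype was not tested and stays open for this count and for the C:G load. For A:T positions the real count was 0, so all 35 gave as many by construction and the count says nothing about chance, and the highest other, which parts replicate numbers 1 and 2 from 3 and 4, gave 3.

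At the polymorphic positions, which the report's comparisons do not use, a second base was read in UNG-/- replicates 1, 2 and 4 and, at a lower level, in AID-/- libraries. At position 225 it was carried by 48.0%, 48.2% and 45.7% of reads in UNG-/- replicates 1, 2 and 4 and, with the bases exchanged, by 2.078% and 2.0701% in AID-/- replicates 1 and 2. At position 486 the shares were 43.5%, 44.3% and 41.8% in the same UNG-/- libraries and 2.34% and 2.30% in the AID-/- libraries. UNG-/- replicate 3 had 0.153% and 0.123% at these positions, and the UNG+/+ libraries 0.0873% to 0.256% and 0.08995% to 0.241%. At positions 376, 454 and 455 the second base was rarer in UNG-/- replicates 1, 2 and 4, with 11.7% to 14.4%, 2.02% to 3.55% and 1.96% to 3.55%, and 61.8% to 63.7% of their bases passed the quality filter there, against 98.8% to 99.2% in UNG-/- replicate 3. AID-/- libraries had 0.367% to 0.461%, 0.0804% to 0.142% and 0.0918% to 0.142% at these positions, of which the 0.0804% at position 454 lay below the 0.113% of UNG-/- replicate 3.

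AID-/- libraries mainly carried the bases of the second haplotype of UNG-/- replicates 1, 2 and 4, and their rare bases were those of UNG+/+ libraries. Comparisons with AID-/- libraries and subtractions of their mean are thus not matched for haplotype, and its effect was not tested. The rare haplotype in the AID-/- libraries may come from reads of another library. Carry-over from an UNG-/- library large enough to give it would bring at least 2.15 transitions per 10000 at AGCT positions, above the 1.14 and 1.21 seen in the AID-/- libraries, which argues against that source. Carry-over from UNG+/+ libraries stays open, since the slope of AID-/- on UNG+/+ transitions over the 12 AGCT positions was 1.02% ± 0.731 (SE), too imprecise to be told apart from the 2.074% share. Such a share of its reads would raise the AID-/- value at C:G positions by 0.175 per 10000, to the 4.38 observed. No biological explanation was tested.

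UNG-/- replicate 3 stood above the other UNG-/- libraries at WRC positions next to polymorphic positions, and it alone of the UNG-/- libraries lacked the second haplotype. Its transition level over the mean of the others had a median ratio of 1.47 (1.15 to 1.61) at the 4 positions within 3 bp whose WRC motif is kept on both haplotypes. At 63 positions over 10 bp away it was 0.873 (5th to 95th percentile 0.778 to 1.09). The former 4 were chosen for a kept motif, so loss of the WRC motif cannot act there and does not account for their ratio. At the 3 positions within 3 bp whose motif is lost the median ratio was 1.49 (1.46 to 1.78). The base after the motif changes on the second haplotype at G456, which then is no longer AGCT, and at G487, and this was not tested. That base is kept at G451 and C452, with ratios of 1.42 and 1.15. Loss during processing of reads with a substitution beside a mismatch could lower the heterozygous libraries, whose median log2 ratio over UNG+/+ at 7 WGC positions within 3 bp was 1.02, below the quartiles of 1.16 to 1.77 farther away. Bases were lost to the quality filter in these libraries at positions 376, 454 and 455 and at C452 (65.8% to 66.5% passing), yet C452 had the lowest ratio of the 4, 1.15, and G487, with 94.7% to 95.7% passing beside a second base that was largely kept, the highest, 1.61. UNG-/- replicate 3 had 1.63 at the WGC positions, just above its own upper quartile of 1.62 farther away where the test had required a value inside the quartiles, so loss beside a mismatch stays open. It would bear on G456 and on G451, C452, C457 and C488, the 4 WRC positions that did not pass with all substitutions counted. With transitions alone only C452 of these 4 did not pass. No biological explanation was tested.

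The rise in UNG-/- cells was larger at WAC (AAC and TAC) than at WGC (AGC and TGC) positions, a comparison made after the motif values were seen. Transition excess went from 14.8 to 75.05 per 10000 (5.07-fold) at 30 WAC positions and from 23.7 to 69.97 (2.95-fold) at 44 WGC positions, and log2 WAC over WGC was 0.10 ± 0.0711 in UNG-/- and -0.68 ± 0.0609 in UNG+/+ cells (SD, n = 4 each, exact two-sided permutation p = 0.0286 for the difference of 0.78), with 0.82 and 0.73 within replicate numbers 1 and 2 and 3 and 4. Background at the motif would remove the difference where AID-/- cells had at most 1 transition per 10000, yet it was 1.04 there, and place along the fragment would remove it within parts of the fragment, yet the smaller of the differences was 0.73. Without positions within 3 bp of a polymorphic position it was 0.70, so these 3 technical explanations are argued against. That UNG acted more at WAC than at WGC uracils is a hypothesis that no table here tests (it would need uracil removal measured at each motif), and a strain difference linked to genotype stays open, since 3 of 4 UNG-/- libraries carried another haplotype, although UNG-/- replicate 3, which did not, had -0.01 against -0.60 for the highest UNG+/+ library.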

How the results depend on the processing

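The background from each library's own SYC positions, C:G to A:T left out, the removal of positions within 3 bp of a polymorphic position and the block of replicate pairs were chosen after the results were seen. Of the alternatives to results that answer a comparison, 243 kept direction and side of the threshold or, for counts and the correlation, stayed near the main value. A further 6 lost the threshold, 6 gained it, 5 changed direction and 5 moved in value or count. For named classes and positions 702 kept, 34 lost, 3 gained and 5 changed direction. Some could not change, as the library left out did not enter the result or too few AID-/- libraries were compared. The tally is therefore no measure of robustness. Where not said otherwise, the cause was not tested.

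Pairing by replicate number left the C:G difference at 16.3 per 10000 and the transition share at 20.3 points, each with an exact p of 0.125, and 0 motif classes, because 4 pairs cannot give less. TMM centres the positions by construction and gave 126 (53 higher, 73 lower), 197 (88, 109) and 141 (70, 71) calls for UNG-/- against UNG+/+, UNG-/- against AID-/- and UNG+/+ against AID-/-. Transitions alone gave 200 calls between UNG genotypes and 154 for UNG+/+ against AID-/-, a WRC preference difference of -0.30 that passed, and 0.66 at G410. Limma on the fraction gave 0 calls for UNG+/+ against AID-/-. The WRC preference difference was 0.64 without subtraction, -0.16 with own SYC background and -0.40 with C:G to A:T left out, the latter 2 with an exact p of 0.0286. The C over G difference was 0.0126 without the 5% of positions highest in AID-/- cells and -0.32 with own SYC background (exact p = 0.0286). A:T to G:C differed by -0.00203 with pooled reads. Leaving out each replicate gave 14.6 to 18.6 for the C:G difference, with an exact p of 0.0571 without any UNG+/+ replicate, -2.36 to -0.23 for WRC preference, -0.221 to -0.0945 for C over G (without UNG+/+ replicate 3 an exact p of 0.0286 for each), -0.0101 to 0.0212 for A:T to G:C and 0 to 1 A:T calls (1 without UNG-/- replicate 2). It also gave 17.3 to 22.2 points for the transition share, 7 to 8 motif classes and 119 to 153 calls between UNG genotypes. The range for WRC preference covers the 9 fits in which its ratio was defined. For the C:G difference the genotypes did not overlap whichever replicate was left out. Of simulated 1.5-fold rises, 55% at C:G and 35% at A:T positions were recovered, and no simulation parted depth from the spread between libraries as the limit.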

Other observations

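All comparisons in this part were chosen after the values were seen, and no hypothesis was tested. In UNG+/+ cells the class values of transversions at AAC rested largely on 1 position, C506. At AAC positions the excess of C:G to G:C was 4.16 ± 1.39 per 10000 and that of C:G to A:T 0.610 ± 0.431 (SD, n = 4 each), but without C506 they were 1.67 ± 0.470 and 0.325 ± 0.339. At TGC positions the same types had 2.08 ± 0.491 and 2.62 ± 0.326, and without G451, which lies 3 bp from a polymorphic position, the former was 1.29. AGC positions had 3.69 and 2.42, TAC positions 1.44 and 1.02, and AGCT positions 7.48 and 4.02. Transversions made up 25.0% of the excess at AAC (14.4% without C506), 24.1% at TGC, 24.5% at AGCT, 18.1% at AGC and 13.8% at TAC positions. C:G to A:T background differed between libraries, from 1.44 to 4.13 per 10000 at SYC positions of UNG+/+ libraries, which bears on the second type more than on the first.

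AGCT is a palindrome, so each copy offers a WRC cytosine on both strands, and the 6 copies differed in which strand was the more substituted. At C282 the transition excess was 1.51 times that of G281 in UNG+/+ and 2.11 times in UNG-/- cells, and it was higher in 8 of 8 UNG libraries. C392 over G391 had ratios of 2.66 and 2.63 and C535 over G534 of 1.92 and 1.698, again higher in 8 of 8 libraries each. The opposite held in all 8 libraries for C457 over G456, with 0.367 and 0.309, and C462 over G461, with 0.521 and 0.542, the former pair lying within 3 bp of a polymorphic position. C26 over G25 had 1.34 and 0.970, with C higher in 5 of 8 libraries.

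Across the 74 WRC positions, which are not independent replicates, transition excess had a Spearman rho with position along the fragment of 0.377 in UNG+/+ and 0.221 in UNG-/- cells and a Pearson r of 0.262 and 0.127, with no test. The log2 fold change of transitions between the genotypes ran the other way, with a rho of -0.354 and an r of -0.372 over 73 WRC positions. Its rho was -0.328 over WAC and -0.0337 over WGC positions. C530 (AGCA) had 26.8 substituted reads per 10000 in AID-/- cells, against a mean of 5.11 over WRC positions.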
